A study of Homo sapiens with 4 samples.

How the data were processed

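RNA was measured by sequencing in WI-38-hTERT cells, a human fibroblast line immortalized with telomerase. The series holds 4 libraries in 2 groups, with 2 libraries from cells kept at 37 °C and 2 from cells held at 40 °C for 2 h. Per the labels' protocols, total RNA was depleted of ribosomal RNA and made into stranded libraries. For the heat treatment the medium was exchanged for fresh medium that had been warmed to 40 °C. Whether the control dishes also received fresh medium is not given in the sources used here. The labels do not say whether the 2 libraries of a group came from separate cultures.

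Per the submitters' processing notes, the tools were STAR 2.7.0d, RSEM 1.3.1 and edgeR, with the human build hg19. No role or order of these tools is given, and the annotation and filters are not given in the sources used here. The deposited table lists 17750 genes by symbol, under a column heading that speaks of Ensembl identifiers, with 1 column named for each library. The values the authors deposited are a signal on the scale of reads per gene, fractional and not divided by library size or gene length. They are not read counts of single libraries. At 37 °C the first column is 1.205 times the second for each of the 16807 genes above 0, and at 40 °C the ratio is 0.939 for each of the 16921 genes above 0. The largest relative deviation from these ratios was 2.0e-14, which is rounding error. Each gene therefore has 1 independent value per group, as the fitted means of a group model have, and the table carries no spread between replicates.

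For this reason the tests planned before the data were examined (a limma or count-model test with Benjamini-Hochberg adjustment, and set tests on the gene lists) were not run, and no p-value, standard deviation or number of changed genes by a test is given. The comparison was described by size. The 2 columns of a group were summed and divided by the group's total, giving fitted reads per 1000000 (fpm). Genes with at least 1 fpm in either group were kept, which left 12261 genes and removed 5489. The log2 difference is log2 of the value at 40 °C plus 1, minus log2 of the value at 37 °C plus 1, all in fpm. This pseudocount of 1 understates the difference of low genes. A fold in the text is the plain ratio of the fpm values. A gene counted as at least 2-fold higher or lower when its log2 difference reached 1 in size. Counts of genes at 1.5-fold, or within it, likewise use the log2 difference and not the plain ratio. A low gene can therefore pass 1.5-fold by ratio without being counted. ANKRD37 (0.674 and 1.41 fpm) was 2.085-fold higher by ratio but had a log2 difference of 0.52.

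The columns sum to 34673743 and 28784763 at 37 °C and to 28902066 and 30774255 at 40 °C. Genes with a single read in a group lie close to 1 in the group sums, so 1 unit is close to 1 read. Intervals of a fold are 95% Clopper-Pearson intervals from the rounded group sums of both libraries, conditional on their total. They cover counting error only, are approximate because the values are fitted, and leave out the spread between cultures and libraries, which is expected to be larger and cannot be measured in this table. Data with counting error only were simulated on 12261 genes for this comparison. The size rule found 100% of 100 genes changed 4-fold and 98% of 100 genes changed 2.5-fold. Of 12061 unchanged genes, 0% passed it. The changed genes were drawn only from genes well above the filter at 37 °C, where such changes nearly always reach the rule by arithmetic. Lower genes can be missed: HIF1A-AS2 (0.317 and 1.40 fpm) was 4.41-fold higher but had a log2 difference of 0.86.

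The 32 gene lists were fixed before the data were examined. Some share members, among them the classic HSF1 targets with the chaperone lists. For each list with 3 or more members passing the filter (28 lists), the median log2 difference was set against 10000 random lists of the same size, matched on expression in 20 bins, and its percentile is given. A percentile describes these values and is no test across replicates. The named genes were fixed as the 10 largest differences in each direction, a fixed set of heat, H3.3 chaperone and stress genes, and examples from each list. Since no test could be run, the examples are the 3 members with the largest differences and the largest one in the other direction, and a few of these examples are left out of the text. The rule's floor of 1 CPM for the leading genes was applied as 1 fpm. H3F3A, one of the fixed genes, is not analysed here, nor are the mitochondrially encoded genes. Symbols are printed as the table gives them, and 15806 of them (89.0%) were found in a current gene name table, older symbols included. No coordinates are given because the annotation at hand is on another build than hg19. GENCODE release 29 served only for exonic length and GC content. Reads shared between near-identical copies, or between a gene and a longer conjoined transcript that contains it, can be split in different ways by the counting, and such genes are marked as uncertain.

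Alternatives fixed before the data were examined were no filter, a filter of 10 fpm, median-of-ratios scaling, quantile normalization and pseudocounts of 0.1 and 5. Leaving out conjoined genes and a 1.5-fold rule were added after seeing the data. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.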

Results

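The transcriptome of WI-38-hTERT fibroblasts was compared between cells kept at 37 °C and cells held at 40 °C for 2 h, a mild heat dose that the study uses as a priming stress. Each group had 2 libraries, and their columns summed to between 28784763 and 34673743 fitted reads. The deposited values hold 1 independent value per gene and group, so every value below is a group value with no replicate error, and no difference was tested against the spread between cultures. The 40 °C cells also received fresh medium with the heat, and it is not known here whether the controls did. No difference below can therefore be assigned to temperature alone. Intervals in parentheses are 95% counting intervals of a fold. All levels are fitted reads per 1000000 of the group's total (fpm).

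At 40 °C inducible HSP70 genes and a few genes of the endoplasmic reticulum (ER) stress response, led by HERPUD1, stood far above their 37 °C level, while several immediate early and inflammatory genes stood below it. Of 12261 genes passing the filter, 47 were at least 2-fold higher at 40 °C and 17 were at least 2-fold lower. The counts were 52 and 17 with median-of-ratios scaling and 51 and 16 with quantile normalization. They depended more on how low genes were treated, with 90 and 40 for a pseudocount of 0.1, 24 and 6 for a pseudocount of 5, and 29 and 8 for a filter of 10 fpm. Relative to each group's total, the rest of the transcriptome differed little. By log2 difference, in which the pseudocount shrinks low genes, 97.46% of genes lay within 1.5-fold. The median log2 difference was -0.03, and 90% of genes lay between -0.35 and 0.31. Because each group was divided by its own total, a change common to all genes would not show. Across genes, the log2 values of the groups had a Pearson correlation of 0.993, where genes are not independent replicates.

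**Figure D1:**
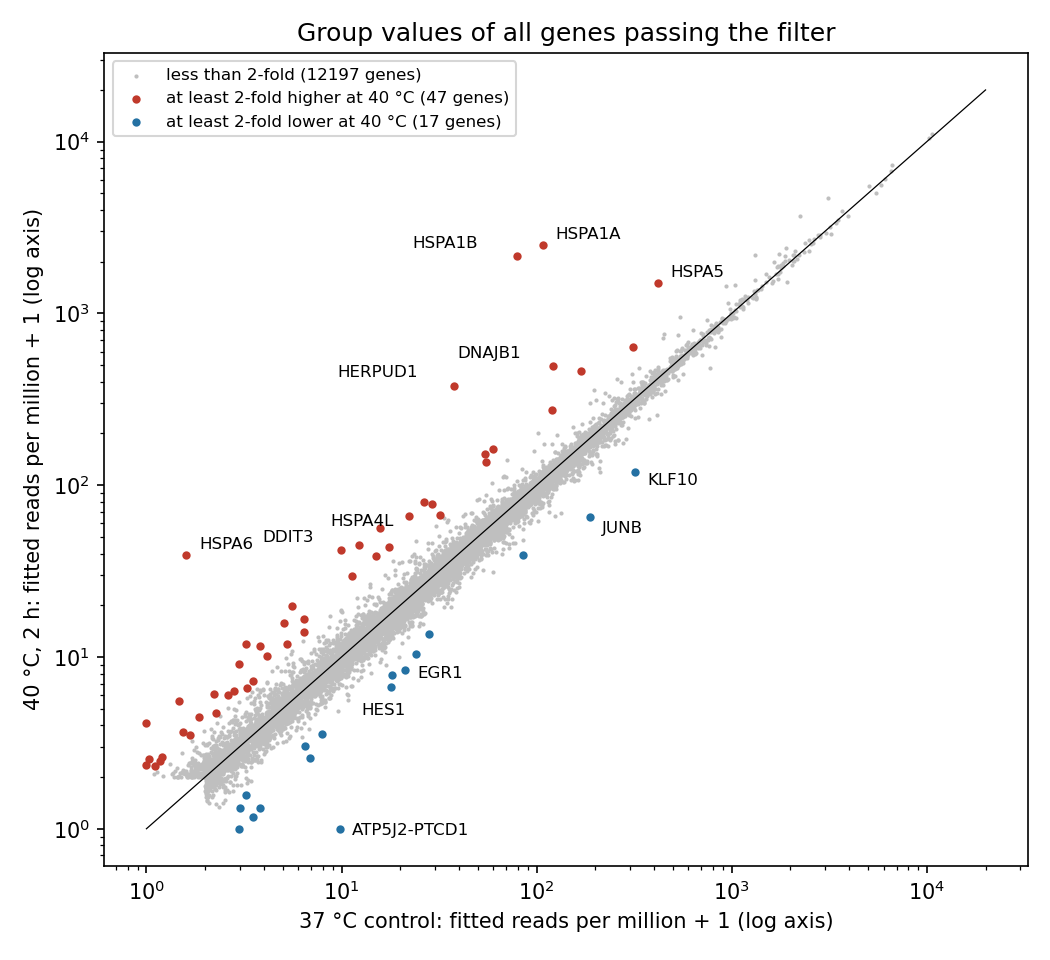
Fitted reads per 1000000 (fpm) plus 1 at 37 °C (x axis, log scale) and at 40 °C (y axis, log scale), with 1 point per gene for the 12261 genes passing the filter and a line of equality. The 47 genes at least 2-fold higher at 40 °C are red and include HSPA1A, HSPA1B, HSPA6 and HERPUD1, and the 17 at least 2-fold lower are blue and include JUNB, KLF10 and EGR1.

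The largest differences belonged to the inducible HSP70 genes, whose products refold damaged proteins in the cytosol and nucleus. HSPA1A was at 107 fpm at 37 °C and 2499 at 40 °C, a 23.4-fold difference (22.8 to 24.0). HSPA1B went from 78.3 to 2157 fpm, or 27.5-fold (26.8 to 28.3). These genes are near-identical copies whose reads can be split in different ways, so their sum is safer, and it was 25.1-fold higher and took 0.466% of all fitted reads at 40 °C. HSPA6, a strictly inducible HSP70 gene, was barely present at 37 °C (0.603 fpm) and reached 38.2 fpm at 40 °C, 63.3-fold higher (46.3 to 90.3). Its near copy HSPA7 adds little, and the sum of both was 63.1-fold higher. The constitutive HSP70 gene HSPA8 was 1.50-fold higher (1.49 to 1.51), from 3131 to 4688 fpm. In the list of HSP70 and HSP110 chaperones, 5 of 13 members were at least 2-fold higher, none was 2-fold lower, and the median log2 difference was 0.58, at percentile 100 among matched random lists. The other members above 2-fold were HSPA4L at 3.90-fold (3.59 to 4.24) and HSPH1, which encodes HSP110, at 2.76-fold (2.699 to 2.82). HSPA2 was the member that stood lowest, at 0.922-fold.

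Co-chaperones of HSP70 and HSP90 differed selectively. Of 16 DNAJ co-chaperone genes, 3 were at least 2-fold higher and 13 were not, and the list's median was only 0.04 (percentile 98.5). Those 3 were DNAJB1, which encodes the HSP40 partner of inducible HSP70, at 4.09-fold (3.99 to 4.20), DNAJB4 at 2.498-fold and DNAJA1 at 2.03-fold (2.00 to 2.07). DNAJC9, a histone-binding family member, was at 0.866-fold. Of 20 genes for HSP90 and its co-chaperones, 3 were at least 2-fold higher and 17 stood above their 37 °C value, with a median of 0.30 (percentile 100). CHORDC1 was 2.83-fold higher, BAG3, which couples HSP70 to autophagy, was 2.76-fold higher (2.66 to 2.87), and the HSP90 partner FKBP4 was 2.30-fold higher. HSP90AA1, the inducible cytosolic HSP90 gene, was 1.67-fold higher (1.66 to 1.68), from 1316 to 2197 fpm, whereas FKBP5 was at 0.782-fold. Among 17 chaperonin genes no member reached 2-fold, and the median was 0.19 (percentile 100). The mitochondrial chaperonin genes HSPD1 (1.69-fold) and HSPE1 (1.61-fold) led this list, CCT4 of the cytosolic ring was at 1.22-fold, and PFDN1 was at 0.896-fold. Of 6 small heat shock protein genes 3 were higher and 3 lower, with a median of 0.01 (percentile 66.9) that became 0.48 with a filter of 10 fpm and -0.05 with no filter. HSPB1 was 1.41-fold higher (1.38 to 1.44), HSPB8 was also 1.41-fold higher, CRYAB was at 1.05-fold with an interval that includes 1 (0.882 to 1.25), and HSPB11 was at 0.826-fold.

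The list of classic targets of HSF1, the main heat shock transcription factor, shares most of these genes. Of its 30 members, 28 were higher at 40 °C, 22 were at least 1.5-fold higher and 13 at least 2-fold higher, and the median log2 difference was 0.95 (percentile 100). IER5, at 0.919-fold, was the lowest member. The heat shock factor genes differed less: HSF1 was at 1.08-fold (1.04 to 1.12) and HSF2 at 0.811-fold (0.737 to 0.891). HSBP1L1, a gene related to the HSF1-binding protein gene HSBP1, was at 0.878-fold. The 4 members of this list passing the filter had a median of -0.08 (percentile 31.8), or 0.02 with no filter.

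**Figure D2:**
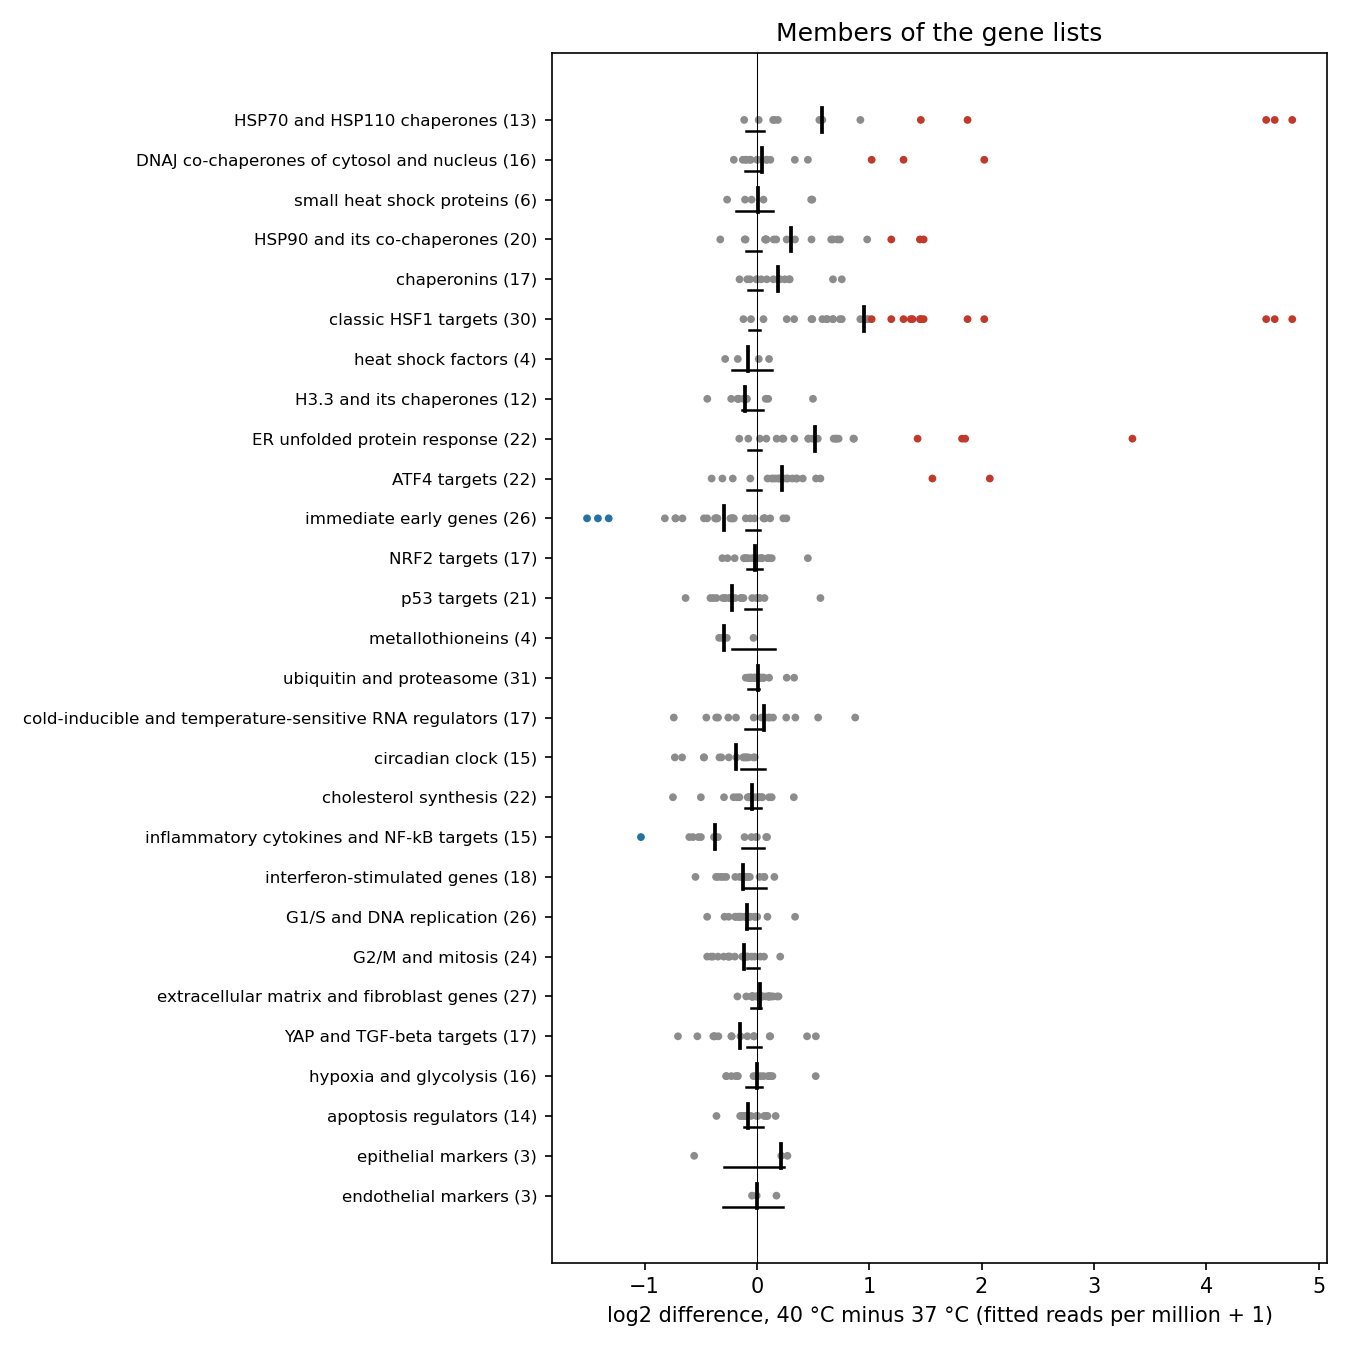
Log2 difference between 40 °C and 37 °C (x axis) for each gene passing the filter in 28 gene lists. Rows are the lists with 3 or more such members, with their number in brackets. Points are genes, red if at least 2-fold higher and blue if at least 2-fold lower, vertical bars are list medians, and the thin horizontal line under each row spans the central 95% of medians of matched random lists. The median of the classic HSF1 targets is 0.95 and that of the immediate early genes is -0.29.

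Genes of the ER unfolded protein response were higher together. Of 22 members 20 were higher at 40 °C, 10 were at least 1.5-fold higher and 4 at least 2-fold higher, with a median log2 difference of 0.52 (percentile 100). HERPUD1, an ER membrane protein that takes part in ER-associated degradation, was 10.4-fold higher (9.96 to 10.9), from 36.5 to 380 fpm. HSPA5, which encodes the ER chaperone BiP, was 3.62-fold higher (3.57 to 3.67), from 416 to 1507 fpm, and SDF2L1, an ER chaperone partner, was 3.72-fold higher (3.46 to 4.003). The fourth, named here because the count is small, was the BiP co-chaperone DNAJB9 at 2.76-fold. ERN1, which encodes the ER stress sensor IRE1, was at 0.887-fold. Of 22 targets of the stress transcription factor ATF4, 18 were higher, but 2 reached 2-fold, and the median was 0.22 (percentile 100). These were DDIT3, which encodes the transcription factor CHOP, at 4.57-fold (4.17 to 5.01), and the mTORC1 inhibitor gene DDIT4 at 3.04-fold (2.86 to 3.24). SESN2 was at 1.50-fold, PPP1R15A at 0.755-fold and ATF3 at 0.956-fold, the last with an interval that includes 1 (0.855 to 1.07).

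Immediate early genes, which respond within minutes to growth factors and stress, were lower as a list. Whether the fresh medium given with the heat plays a part in this stays open. Of 26 members 20 were lower at 40 °C, 7 by at least 1.5-fold and 3 by at least 2-fold, with none 1.5-fold higher, and the median log2 difference was -0.29 (percentile 0). The AP-1 gene JUNB was at 186 fpm at 37 °C and 64.6 at 40 °C, 2.88 times lower. KLF10, a gene induced by TGF-beta, was 2.68 times lower, from 317 to 118 fpm, and EGR1 was 2.699 times lower, from 20.1 to 7.44 fpm. FOS was low in both groups (2.28 and 1.82 fpm), with an interval of the fold that includes 1 (0.622 to 1.04), and NR4A3 was at 1.27-fold. Inflammatory cytokine and NF-kB target genes were also lower, 13 of 15 of them, with a median of -0.37 (percentile 0). The neutrophil chemokine gene CXCL8 was 2.13 times lower, the NF-kB inhibitor gene NFKBIA 1.53 times lower and PTGS2 1.59 times lower, while NFKB2 was at 1.07-fold with an interval that includes 1 (0.996 to 1.14). Interferon-stimulated genes had a median of -0.12, within the range of random lists (percentile 3.26), or -0.07 with a pseudocount of 5. By log2 difference IFIT3 (0.672-fold), IFIT1 (0.761-fold) and DDX58 (0.777-fold) were lowest. IFI27 was highest, at 1.15-fold with an interval that includes 1 (0.942 to 1.42). The YAP and TGF-beta target list had a median of -0.15 (percentile 0.04), with AMOTL2 at 0.613-fold and ID1 at 0.691-fold but ID3 at 1.44-fold.

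Among the genes with the largest lower values, HES1, a Notch target, was 2.998 times lower, from 16.9 to 5.65 fpm. Besides HES1, JUNB, KLF10 and EGR1, the leaders in that direction are uncertain. CDRT4 went from 2.83 to 0.324 fpm, and whether its reads were split with a longer conjoined transcript was not examined. ATP5J2-PTCD1 went from 8.80 to 0.00184 fpm while PTCD1, which it contains, went from 5.45 to 15.6. GJA9-MYCBP went from 23.1 to 9.37 fpm while MYCBP went from 4.59 to 18.7, and their sum with GJA9 was at 1.01-fold. SERF1A was at 1.97 fpm at 37 °C and listed at 0 at 40 °C, but summed with its copy SERF1B it was at 0.920-fold. GTF2H2C went from 2.503 to 0.178 fpm and was at 0.837-fold when summed with GTF2H2 and GTF2H2B. FAM72C went from 5.93 to 1.57 fpm, whereas FAM72D went from 1.98 to 8.10 and FAM72A to FAM72D together were at 1.25-fold. Among the leaders in the other direction, TMEM189-UBE2V1 (listed at 0 at 37 °C and at 3.13 fpm at 40 °C) and MINOS1-NBL1 (0.469 and 4.55 fpm) are conjoined transcripts whose reads can also be assigned to their parts, and LOC100129917 was 4.86-fold higher (4.06 to 5.89).

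The study concerns HIRA, the chaperone that deposits histone H3.3 outside replication. HIRA mRNA was at 1.06-fold with an interval that includes 1 (0.986 to 1.13), at 25.5 and 27.0 fpm. Its complex partners UBN1 (1.07-fold, 1.03 to 1.12) and CABIN1 (0.935-fold, 0.891 to 0.982) and the donor chaperone ASF1A (0.936-fold, 0.870 to 1.01) were all within 1.1-fold. The H3.3 gene H3F3B was at 0.889-fold (0.873 to 0.904). No member of the list of 12 H3.3 and histone chaperone genes reached 1.5-fold, and its median was -0.11 (percentile 6.64). UBN2 at 1.45-fold stood highest and CHAF1B, of the replication-coupled chaperone CAF-1, lowest at 0.720-fold, followed by ASF1B at 0.848-fold.

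RNA regulators that respond to temperature went both ways. The cold-inducible RNA-binding protein genes CIRBP (0.785-fold, 0.758 to 0.812) and RBM3 (0.838-fold, 0.822 to 0.854) were lower at 40 °C. The splicing factor gene SRSF5 was 1.68 times lower, and the splicing factor kinase genes CLK4 (1.91-fold, 1.74 to 2.10) and CLK1 (1.47-fold) were higher. The list as a whole had 10 members higher, 7 lower and a median of 0.06 (percentile 99.7). All 15 circadian clock genes passing the filter, of 18 listed, were lower, with a median of -0.18 (percentile 0.36). This median became -0.10 with a filter of 10 fpm and -0.12 with no filter. BHLHE40 (1.68 times lower), RORA (1.85 times lower) and CIART (1.58 times lower) led the list.

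Other stress programmes differed in direction and size. Of 17 targets of NRF2, the oxidative stress factor, none reached 1.5-fold, and the median was -0.02 (percentile 58.0). HMOX1 was 1.39-fold higher (1.29 to 1.50), while SLC7A11 (0.807-fold) and GCLC (0.829-fold) were lower. Of 21 p53 targets 17 were lower, with a median of -0.23 (percentile 0) that became -0.14 with a pseudocount of 5. Among them were TP53INP1 (1.61 times lower) and ZMAT3 (1.34 times lower), while CDKN1A was at 0.904-fold. SESN2, which also stands in the ATF4 list, was at 1.50-fold. The 4 metallothionein genes passing the filter were all lower, with a median of -0.29 (percentile 0.55) that became -0.07 with no filter. Among them were MT1E (0.789-fold), MT2A (0.829-fold) and MT1X (0.705-fold). The 31 ubiquitin and proteasome genes had a median of 0.01 (percentile 94.6). UBB, a ubiquitin gene, was at 1.202-fold and stood above the proteasome subunit genes, of which PSMD3 was highest at 1.08-fold and PSMD12 lowest at 0.932-fold. Hypoxia and glycolysis genes had a median of 0.00 (percentile 76.9), with PDK1 (0.823-fold) and KDM3A (0.819-fold) below and ANKRD37 (0.674 and 1.41 fpm) above. Apoptosis regulators had a median of -0.08 (percentile 13.1), with BBC3 at 0.711-fold, BIRC2 at 0.901-fold and MCL1 at 1.12-fold. Cholesterol synthesis genes had a median of -0.05 (percentile 39.7), although INSIG1 (1.71 times lower) stood apart and PMVK was at 1.33-fold.

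Mitotic genes were slightly lower. The G2/M and mitosis list had 21 of 24 members lower and a median of -0.12 (percentile 0.22), with KIF23 (0.734-fold), KIF11 (0.752-fold) and CENPE (0.761-fold) lowest and CENPA at 1.16-fold. The G1/S and DNA replication list had 23 of 26 members lower and a median of -0.09, within the range of random lists (percentile 3.63), with CCNE2 at 0.724-fold, MCM6 at 0.813-fold and CDC6 at 1.27-fold. No member of either list reached 1.5-fold.

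Fibroblast identity differed little between the groups. The 27 extracellular matrix and fibroblast genes had a median of 0.03 (percentile 97.3), and the leading members were COL4A2 (1.14-fold), COL5A1 (1.13-fold) and PDGFRA (0.886-fold). Markers of other cell types were low or differed little. Some stood well above the filter at 37 and 40 °C, among them TEK (195 and 189 fpm), CNN1 (154 and 157 fpm) and LMOD1 (92.9 and 94.4 fpm). Of 12 epithelial markers 3 passed the filter, with a median of 0.22 (percentile 96.5), or 0.04 with no filter: KRT8 at 1.23-fold, KRT18 at 1.17-fold and CLDN4 at 1.09 and 0.419 fpm. Of 10 endothelial markers 3 passed, with a median of 0.00 (percentile 59.4), among them TEK at 0.970-fold, EGFL7 at 0.998-fold and VWF at 1.28-fold with an interval that includes 1 (0.879 to 1.87). The leukocyte list left CD4 (0.749-fold) and CD68 (0.897-fold), the muscle list CNN1 (1.02-fold) and LMOD1 (1.02-fold), and the neural list TUBB3 (1.23-fold) and MBP (0.942-fold).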

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

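Replicate spread limits every value, since the table holds 1 independent value per gene and group. No paired analysis was possible because the columns of a group are proportional, so a replicate block has nothing to remove. Leaving out 1 library moved fpm values by a relative 6.0e-15 at most, by the table's construction, and says nothing about stability. The planned tests, their thresholds and the comparison with a deposited test were not run. The count of 47 genes at least 2-fold higher became 29 with a filter of 10 fpm, 90 with a pseudocount of 0.1, 24 with a pseudocount of 5 and 190 with a 1.5-fold rule, the last added after seeing the data. The count of 17 lower genes became 8, 40, 6 and 122 under the same settings. Without conjoined genes, a setting also added after seeing the data, the counts were 41 and 15. That setting removes only the conjoined symbols themselves. Their parts PTCD1 and MYCBP and the copy FAM72D stay among the higher genes. The copies SERF1A, GTF2H2C and FAM72C stay among the lower ones, so these counts still hold genes marked as uncertain. Fewer genes pass the stricter filter, and a larger pseudocount shrinks low genes by construction. Of the 64 genes at least 2-fold either way, all 64 stayed so under median-of-ratios scaling and 62 under quantile normalization, and 30 under a pseudocount of 5. No named gene past 2-fold and no list median outside the random range changed direction under the alternatives run. Of 165 list medians under alternatives, 158 stayed inside the bootstrap interval of the main one, but these intervals are wide for short lists. Small heat shock proteins went from 0.01 to 0.48 with a filter of 10 fpm and to -0.05 with no filter, and circadian clock genes from -0.18 to -0.10 with a filter of 10 fpm. With no filter, metallothioneins went from -0.29 to -0.07, epithelial markers from 0.22 to 0.04 and heat shock factors from -0.08 to 0.02. A pseudocount of 5 brought immediate early genes from -0.29 to -0.20 and p53 targets from -0.23 to -0.14, and quantile normalization brought the temperature-sensitive RNA regulators from 0.06 to 0.11, DNAJ co-chaperones from 0.04 to 0.08, H3.3 and its chaperones from -0.11 to -0.07, cholesterol synthesis genes from -0.05 to -0.01 and extracellular matrix genes from 0.03 to 0.00. The last became 0.06 with median-of-ratios scaling, and apoptosis regulators went from -0.08 to -0.03 with no filter. The NRF2, hypoxia and endothelial medians, all close to 0, changed sign under some settings, as that of the small heat shock proteins did. Median-of-ratios scaling shifts all genes nearly alike, with the median of all genes going from -0.03 to -0.01, so the shifts under it say little about single lists. Quantile normalization also moved the median of all genes to -0.01, so the shifts of lists under it include this common part. The ubiquitin and proteasome median of 0.0072 became 0.037 with median-of-ratios scaling and 0.030 with quantile normalization. Under the same scalings the G1/S median of -0.092 became -0.0650 and -0.071, and the G2/M median of -0.118 became -0.089 and -0.087. The interferon-stimulated median of -0.12 became -0.0703 with a pseudocount of 5.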

Other observations

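The gene families in this part were chosen after the data had been examined, as were all tests on the table's columns and on conjoined genes and the comparison with S-phase genes. The tests of length and GC content and of copies on histone genes were written down before their results were seen. HIST-named histone genes, most of them known to be expressed in S phase, were lower at 40 °C in 59 of 66 cases. Their median log2 difference was -0.34, at percentile 0 of random lists whose medians ran from -0.07 to 0.00. HIST1H1D (0.596-fold), HIST1H2BH (0.603-fold), HIST1H1C (0.648-fold) and HIST1H2AK (0.573-fold) were lowest, and HIST1H4L (1.27-fold) and HIST1H1A (1.24-fold) highest. KLF-named transcription factor genes (11 of 12 lower, median -0.16, percentile 0.75) and DUSP-named phosphatase genes (12 of 15 lower, median -0.15, percentile 0.91) went with the immediate early list, with which they share KLF10 and DUSP1. KLF11 was 2.14 times lower and KLF7 1.58 times lower.

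Housekeeping families moved little. The 81 cytosolic ribosomal protein genes had a median of -0.03 (percentile 24.7), the 46 complex I genes one of -0.02 (percentile 81.4) and the 52 EIF genes one of 0.00 (percentile 93.3). Within the last, EIF2AK3, which encodes the ER stress kinase PERK, was 1.79-fold higher (1.69 to 1.88). The 403 ZNF-named zinc finger genes (median 0.01, percentile 100) and 160 antisense transcripts (median 0.05, percentile 99.9) stood slightly above matched lists. DNAJC3-AS1, which neighbours the ER co-chaperone gene DNAJC3, was 4.94-fold higher (3.42 to 7.43) at low levels. Outside the lists, and named after their values were seen, RSRP1 was 3.09-fold higher, THAP2 3.60-fold higher and SNAI1 2.51 times lower.

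The proportional columns of each group were weighed as a question of what the file holds. If the columns were means fitted by a negative binomial group model, a gene with 1 read would take 1 of 2 levels, depending on which library held the read. At 37 °C the common levels of the group sum were 0.950 (200 genes) and 1.06 (240 genes). The dispersion of 3.07 solved from the lower one gave the upper level and both 40 °C levels (0.982 and 1.02) to within 1.6e-05, so the values are consistent with fitted group means. A single library deposited as a rescaled pair would give 1 level for such genes, but the 37 °C levels lie 11.9% apart, which argues against it. The read counts of single libraries for genes of higher expression cannot be solved from these values, because each gene's dispersion is unknown.

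Conjoined genes, whose symbols join those of 2 listed neighbours, made up 0.489% of the genes passing the filter but 12.5% of those at least 2-fold either way (8 of 64, of which 6 were higher and 2 lower). For 3 of these 8 (ATP5J2-PTCD1, GJA9-MYCBP and TMED7-TICAM2) the parts moved the other way by a similar amount in fpm, as a different split of the same reads between overlapping models would give. For MINOS1-NBL1 the parts were higher too (by 7.95 against 4.08 fpm), which such a split alone does not give. For the other 4 the parts were lower by amounts that do not match. Where parts stand far above the conjoined gene, a small difference of their own can hide or mimic an offset. TMED7-TICAM2 counts partly through TMED7, at 337 and 325.5 fpm (0.966-fold), beside TICAM2 at 36.9 and 26.7 fpm. The split therefore stays open. The 60 conjoined genes passing the filter had a median of 0.13, above matched random lists (-0.08 to 0.04), with 40 higher and 20 lower, and without those 8 the median was still 0.11. One hypothesis is that transcription past gene ends was raised at 40 °C, and this median is what it would need, but a shift in fragment length or in how reads were assigned stays open and was not tested.

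For the lower histone genes, the family's median lay at percentile 0 of lists matched on length, GC content and expression level together (random medians from -0.03 to 0.02). This argues against these properties as the whole cause, but only as far as the matching was close. The lists drew on the 100 nearest other genes of each histone gene, and how near these were was not measured. Reads moving between near-identical copies within the family are argued against too, since such moves would leave its summed fpm value unchanged. That sum was lower, with a log2 difference of -0.35. The family was chosen after the data had been examined, so a lower sum was likely beforehand. Reads moving to copies outside the HIST-named genes were not examined. A smaller share of cells in S phase may contribute. In the G1/S list 23 of 26 members were lower, but its median of -0.09 lay within the range of matched random lists (percentile 3.63). That list therefore gives no firm support. The G2/M and mitosis list, no measure of S phase, had 21 of 24 members lower and a median of -0.12 (percentile 0.22). A smaller share of cells in S phase cannot be told apart from lower histone RNA per cell, since the libraries hold no measure of cell cycle stage. Whether the fresh medium given with the heat played a part stays open, since it is not known here if the control dishes received it too.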
